A study of Mus musculus with 3 samples.

How the data were processed

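Epidermal cells of ear skin from 9-week-old C57BL/6N mice were profiled in 3 single-cell RNA libraries, replicates 1 to 3 of 1 group. Per the labels' protocols, ear skin was split and treated with dispase, the epidermis was lifted off, and cells were released with trypsin and EDTA from its basal side, then frozen until use. This order may favour cells that the enzyme frees from the lower layers, which was not measured. Shares of classes therefore describe the suspension and not the intact tissue. Libraries followed the 10x Genomics V(D)J kit, a droplet method that counts the 5' ends of transcripts, with short cDNA fragments added back after size selection, and were sequenced as paired ends on a HiSeq X, per the labels' protocols. Nothing states whether the replicates came from separate animals, so the p-values may measure only the spread between libraries. Sex is not given.

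Per the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 on genome build mm10, and per the file headers the same version wrote the matrices. The gene annotation version of that reference is not given in the sources used here, nor are other settings. The deposited files hold raw UMI counts per gene and cell for 31053 genes, one matrix per replicate, already limited to barcodes called as cells, with lowest totals of 523, 502 and 500 UMIs. UMIs collapse copies made by amplification, so intervals and bounds from counts cover counting error only. Coordinates come from GENCODE M21.

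Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Of 6078 barcodes, 395 had too few genes and 598 too high a mitochondrial share, 738 in all. Scrublet, as implemented in scanpy 1.11.5, marked 30 doublets among the 5340 that passed, with a doublet rate of 0.8% expected per 1000 cells of a library. The remaining 5310 cells had 931, 2203 and 2176 members per replicate.

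Testing genes between clusters that the same counts defined would overstate differences. The UMI counts of each gene and cell were therefore split at random into equal parts by binomial draws with 50% probability (seed 1). One part served for clustering and the other, held out, for all CPM values and the tests of genes and lists between classes. UMIs counted per barcode or library, including the barcode tests of the closing section, come from the unsplit counts. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2) at resolution 1, leaving out every gene of the gene lists. The split makes sampling noise independent between the parts, but a gene used for clustering still differs between clusters by construction, so named genes that were used are counted.

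Cell type markers were fixed before the data were examined, as were the filters, the clustering settings, 3 of the comparisons with their tests, the planned Langerhans-like comparison, the 25 gene lists, the rule for named genes and the alternatives named first below. The rule that turns marker levels into names was set after seeing the data. In its first step a cluster took the name of a class outside the interfollicular epidermis when that class's markers had a mean log2 fold of at least 1 over other clusters, above a floor of 20 CPM, and most markers among its top 10 genes. In its second step the other clusters took the best of the basal, spinous and granular names by mean z-score, with a margin of at least 0.2 and 3 or more markers detected. Clusters with under 0.333 of the library's median UMIs and too few of their own markers on top, or with more markers of another class on top, stayed unnamed.

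Counts of the held-out part were summed per library and class, for classes with at least 10 cells in a library. All classes entered 1 model in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the low-count filter of that package, a quasi-likelihood test and library as a block, since each library gives several classes. The block pairs profiles by construction. Across genes, which are not independent replicates, a library's deviations from the class mean correlated between the compared classes with r from 0.402 to 0.471 for spinous-like with basal-like cells, 0.175 to 0.360 for granular-like with spinous-like cells and 0.0464 to 0.135 for follicle-like with basal-like cells. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p of 0.05. Gene lists were tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. T-like cells reached 10 cells in 1 library, so the Langerhans-like comparison used profiles of at least 3 cells. A sebocyte-like comparison was added after seeing the data.

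CPM values are means over libraries of held-out counts. Where classes are compared they are scaled with TMM. The markers that describe the classes are scaled to plain total UMIs instead, so the values of these scales cannot be set side by side. Where a class had no counts of a gene, the fold is a lower bound that sets 3 counts over the class. With 1 to 3 counts the ratio of pooled counts is given with its exact 95% interval. Bounds and ratios use totals scaled with TMM, so they hold on that scale only. Other folds are fitted values. Named genes are, per comparison, the 6 largest rises and the 6 largest falls among called genes with the same direction in every library and at least 50 CPM in the higher class, without markers, mitochondrial, ribosomal protein, T cell receptor segment and unnamed genes, plus for each list the largest called rise and fall with at least 10 CPM. The list genes Sts, Sprr2g, Raet1a, Ifi30 and Clec7a were absent from the gene table.

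The test's power was measured on simulated counts, drawn from negative binomial distributions with the measured spread and depth and 50 changed genes per fold. Before these changes every class had the same baseline, the mean over the compared classes. The changed genes were taken only from genes above a floor of mean CPM. Power for scarcer genes, and between classes of differing composition, was therefore not measured. A 2-fold change was found for 100% of these changed genes between spinous-like and basal-like cells, 94% between granular-like and spinous-like cells, 22% between follicle-like and basal-like cells and 6% between Langerhans-like and T-like cells. At 4-fold the last 2 figures were 84% and 42%. Of all calls in these 4 simulations, 7 of 197, 10 of 184, 4 of 104 and 5 of 52 were unchanged genes.

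Alternatives planned in advance for the counts and the model were profiles thinned to the same total, leaving out each replicate, a fit of only the 2 classes compared, no low-count filter, no replicate block, scaling to total UMIs without TMM, and DESeq2 1.42.0 with its own size factors. Those for cells and clusters were resolutions of 0.6 and 1.5, all UMI counts for both clustering and test, doublets kept, genes centred on their library mean, list genes kept in the clustering, a mitochondrial limit of 20% and another seed for the split. Added after seeing the data were cells with at least 1500 genes, named genes left out of the clustering, clusters led by cell cycle genes left out, the 3-cell minimum for all comparisons, and an immune fit at 10 cells with T-like cells of 1 library. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9 and statsmodels 0.14.6.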

Results

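Single-cell transcriptomes were collected from the ear epidermis of 9-week-old C57BL/6N mice, an inbred laboratory strain. The samples form 1 group of 3 replicate libraries without any treatment, and the series states its subject as expression in single cells of this tissue. The deposited counts covered 6078 cell barcodes and 68583868 UMIs (unique molecular identifiers, each standing for a captured transcript). Replicate 1 held 1108 barcodes with 15926683 UMIs, replicate 2 held 2477 with 24480473, and replicate 3 held 2493 with 28176712. After filtering, 931, 2203 and 2176 cells were analysed, with medians of 14566, 9227 and 11273.5 UMIs per cell. A single group leaves comparisons between cell classes within the same libraries, which describe how epidermal cell types differ in a suspension of untreated tissue. Effects of dissociation and freezing on expression were not measured.

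Keratinocytes of the interfollicular epidermis made up most of the cells. The SDs of class shares cover replicates only, and several shares moved by more with filters and clustering settings, as given in a later section. Basal-like cells, named for the layer that rests on the basement membrane, took 40.4% ± 2.93 (SD, n = 3) of the analysed cells. They held 15387 ± 1846 CPM (scaled to the class's total UMIs in a library, n = 3) of the basal keratin Krt14, against 274 ± 158 in spinous-like cells. Spinous-like cells took 29.2% ± 1.94. They led in the suprabasal keratin Krt10, with 17963 ± 2091 CPM against 886 ± 202 in basal-like cells. Granular-like cells took 7.76% ± 1.46. Their transcript of loricrin (Lor), the main protein of the cornified envelope, reached 59946 ± 9228 CPM against 436 ± 286 in spinous-like cells. Of the 2104 basal-like cells, 320 lay in clusters led by cell cycle genes, which took 17.7%, 11.5% and 17.6% of the basal-like cells of replicates 1 to 3 (exact 95% intervals 14.1 to 21.8, 9.46 to 13.9 and 15.1 to 20.3).

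Smaller classes came from the hair follicle, the sebaceous unit and the immune cells of the epidermis. Follicle-like cells took 2.10% ± 0.252. These cells carried 187 ± 52.7 CPM of Cd34 and 263 ± 79.2 CPM of Lgr5, both known from follicle stem cells. Sebocyte-like cells took 1.90% ± 0.228 and expressed Krt79 at 2129 ± 1087 CPM and the desaturase gene Scd1 at 2997 ± 2694 CPM. Their cluster was led by 3 follicle markers beside 3 sebocyte markers, so the name covers cells of the upper follicle and its gland. Langerhans-like cells, the antigen-presenting cells of the epidermis, numbered 0, 23 and 20 in replicates 1 to 3. Their shares were 1.04% in replicate 2 (exact 95% interval 0.663 to 1.56) and 0.919% in replicate 3 (0.562 to 1.42). In replicate 1, 0 of 931 cells gives an exact 95% interval of 0 to 0.395%. These cells held 1750.5 ± 506 CPM (n = 2) of langerin (Cd207) and 39015 ± 1235 CPM of Cd74. The level of Cd74 in basal-like cells, 7.87 ± 3.19 CPM, was far lower. T-like cells, with the gamma-delta receptor transcript Trdc at 767 ± 299 CPM (n = 3), numbered 3, 11 and 7.

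Unnamed cells took 17.6% ± 1.62 of the total and lay in 3 clusters. They were kept out of the comparisons by naming thresholds that were set after the data had been seen. The largest, of 585 cells (11.9%, 11.2% and 10.5% of replicates 1 to 3), was led by Pyy, Clca3a2 and Mt4 and scored between basal-like and spinous-like. A cluster of 239 cells (4.83%, 4.72% and 4.14%) had a median of only 1454 UMIs, and one of 98 cells took 1.83%, 2.59% and 1.10%. The former was led by Gm42418, AY036118, Hist1h1b, Mki67 and Krt5, scored highest as basal, and stayed unnamed for its low UMI counts. A spinous-like cluster of 78 cells was led by the stress-associated genes Sprr1b, Krt16 and Stfa1, and it took 0.859%, 0.726% and 2.48% of replicates 1 to 3. The largest basal-like cluster, of 968 cells, was led by the chemokine genes Ccl27a and Cxcl14 and took 10.96%, 24.4% and 15.1% of replicates 1 to 3. The next basal-like cluster, of 598 cells, took 21.6%, 6.08% and 12.1%, so basal-like cells were spread over clusters differently in each replicate.

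**Figure D1:**
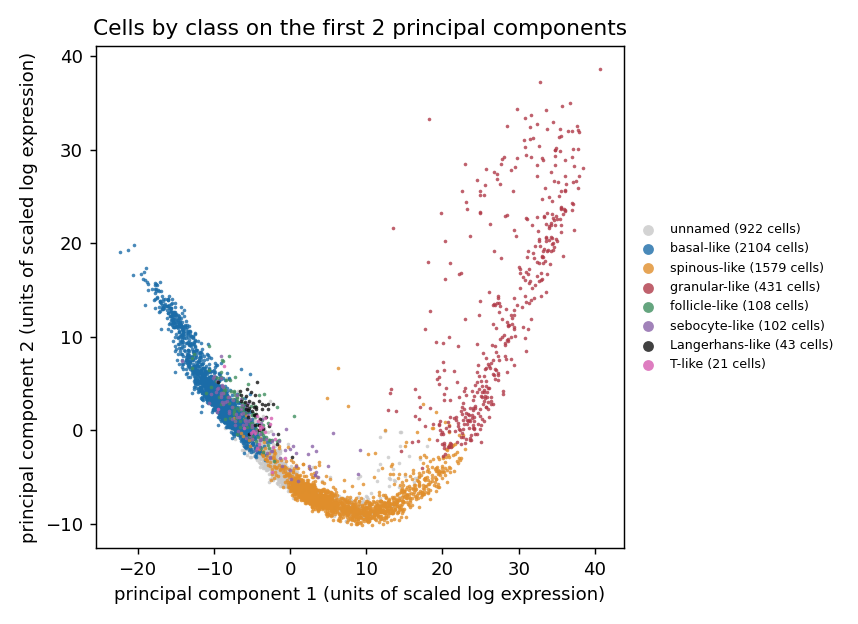
Each point is 1 of the 5310 analysed cells, placed by its first (horizontal axis) and second (vertical axis) principal component, in arbitrary units, and coloured by class. Basal-like (2104 cells), spinous-like (1579) and granular-like (431) cells occupy separate parts of the plot.

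**Figure D2:**
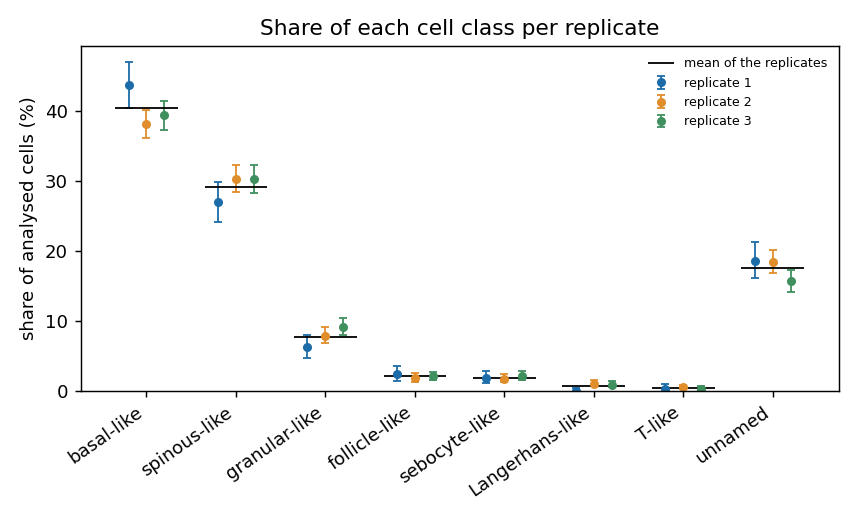
Points give the share of each class in percent of a library's analysed cells (vertical axis) for every replicate, with exact 95% binomial intervals, and black lines give the mean of the 3 replicates. Basal-like cells sit between 38.1% and 43.7%, and Langerhans-like cells are missing from replicate 1.

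The comparison of spinous-like with basal-like cells addresses the first step of epidermal differentiation, in which keratinocytes leave the basement membrane. The unnamed cluster of 585 cells that scored between these classes was left out, so the folds describe the named classes without it. Among the largest rises, Dkkl1, a relative of the Dickkopf family of Wnt regulators, stood at 468 ± 26.9 CPM with TMM scaling (SD, n = 3) in spinous-like cells and 1.23 ± 1.16 in basal-like cells. The difference was 334-fold (log2 8.38 ± 0.26 SE, adjusted p = 2.45e-60). The genes of tissue factor (F3, 245-fold), the secreted Ly6 protein Slurp2 (235-fold), the protease inhibitor Wfdc5 (239-fold), the tight junction protein Cldn4 (215-fold) and the acyltransferase Mboat2 (208-fold) rose by similar factors. The mitotic genes Pbk, Cdk1, Aurkb and Nusap1 led the fall. Cdk1 stood at 0.754 ± 0.723 CPM against 118 ± 30.7 in basal-like cells (log2 -6.97 ± 0.24, adjusted p = 5.27e-56). Beside them fell Igfbp7, an insulin-like growth factor binding protein, 102-fold. Serpinh1, the collagen chaperone Hsp47, went from 62.1 ± 6.74 to 0.546 ± 0.188 CPM (log2 -6.54 ± 0.28).

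Transcripts for contacts with the basement membrane were lower. Among 24 tested genes of basement membrane adhesion, 22 fell, 0 rose and 2 did not pass. Their list test gave adjusted p = 4.45e-10, and adjusted p = 0.0253 with an estimated correlation. Basal-like cells were named in part by other adhesion genes (Itga6, Itgb4, Col17a1 and Dst), so a fall of this list was favoured in advance. Itga3, the integrin subunit that binds epidermal laminin, dropped from 78.2 ± 3.50 to 0.97 ± 0.901 CPM, 64.8-fold lower (log2 -6.02 ± 0.24, adjusted p = 4.27e-49). The list's median was -2.88 log2, or -2.40 with its gene of zero counts at the bound set by 3 counts. Desmosome genes, which join keratinocytes to each other, went the other way. Of these, 9 of 11 rose and 2 fell (list test adjusted p = 0.00532, but adjusted p = 0.0759 with an estimated correlation). The desmocollin Dsc1 was 161-fold higher, and the desmoglein Dsg2 34.2-fold lower.

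Cell cycle genes were almost uniformly lower in spinous-like cells. Of 53, 51 fell (list test adjusted p = 3.99e-20, adjusted p = 0.0759 with an estimated correlation). The single member that rose, the spindle checkpoint kinase gene Ttk, was 2.30-fold higher, at 38.8 ± 3.24 against 16.6 ± 3.51 CPM. Without the clusters led by cell cycle genes, 33 members still fell and the median moved from -4.74 to -1.53 log2 (adjusted p = 2.91e-06, range 8.2e-35 to 2.91e-06 over all alternatives). There Aurkb (adjusted p = 0.0761, range 4.96e-116 to 0.0761) and Nusap1 (adjusted p = 0.198, range 6.99e-196 to 0.198) no longer passed. All 24 tested genes of cholesterol synthesis rose, by a median of 2.73 log2 (list test adjusted p = 5.77e-10, adjusted p = 0.148 with an estimated correlation). Squalene epoxidase (Sqle) rose most in this list, from 6.71 ± 3.61 to 128 ± 24.8 CPM (log2 4.29 ± 0.17). All 8 tested Skint genes, a keratinocyte family related to butyrophilins whose founding member directs the development of epidermal T cells, rose. They did so by a median of 5.86 log2 (list test adjusted p = 2.68e-06, adjusted p = 0.0759 with an estimated correlation). Skint9 stood at 285 ± 10.1 CPM against 2.03 ± 1.05 (log2 7.04 ± 0.20, adjusted p = 5.62e-64). Members of this family are similar in sequence, so counts of single members are less certain.

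Epidermal transcription factor genes moved both ways with an upward balance. They split into 26 rising, 12 falling and 7 not passing (list test adjusted p = 0.00287, adjusted p = 0.0253 with an estimated correlation). Zfp750, a regulator of terminal differentiation, rose from 6.68 ± 2.44 to 218 ± 15.9 CPM (log2 4.98 ± 0.16). Bnc1, a factor of basal keratinocytes, was lower by a ratio of 45.7 (95% interval 15.3 to 224) on 3 spinous-like counts. Ribosomal protein genes rose by a small amount in 47 of 81 cases and fell in 0 (list test adjusted p = 5.94e-05, adjusted p = 0.621 with an estimated correlation), but scaling to total UMIs left 8 rising and 4 falling and turned the median from 0.38 to -0.03 log2 (adjusted p = 0.0532, range 9.15e-10 to 0.0532 over all alternatives). Rps29 was 1.99-fold higher. Immediate early and heat shock genes rose in 21 and fell in 9 of 34 cases, or 15 and 10 scaled to total UMIs. As a list they did not pass (adjusted p = 0.0611, or 0.0174 without replicate 2 and 0.0133 to 0.209 over all alternatives). They ranged from Egr3, 33.6-fold higher, to Hsp90aa1, 3.61-fold lower.

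The remaining lists split and did not pass as lists. Glycolysis genes rose in 3 and fell in 10 of 17 cases (adjusted p = 0.0896, 0.032 without the low-count filter, range 0.032 to 0.186 over all alternatives). Aldoc was 2.90-fold higher and the glucose transporter gene Slc2a1 5.09-fold lower. Nuclear genes of oxidative phosphorylation rose in 13 and fell in 27 of 73 cases (adjusted p = 0.246), whereas scaling to total UMIs made 55 of them fall (adjusted p = 0.00387, range 0.00387 to 0.824 over all alternatives). Ndufa4 was 2.05-fold higher and Uqcrc1 2.96-fold lower. Of 23 Wnt pathway genes, 6 rose and 9 fell (adjusted p = 0.246), or 4 and 14 scaled to total UMIs. Lgr6, an R-spondin receptor gene of stem cells, fell most, from 52.9 ± 8.58 to 0.744 ± 0.925 CPM. Of 16 Notch pathway genes, 6 rose and 5 fell (adjusted p = 0.636). The receptor gene Notch3 was 9.04-fold higher and Lfng, which modifies Notch receptors, 61.4-fold lower. The Notch list's median (0.16) and mean (-0.28) differed in sign, its test pointed up, and scaling to total UMIs gave a median of -0.25. Epidermal cytokine and chemokine genes rose in 9 and fell in 10 of 22 cases (adjusted p = 0.542), or 6 and 11 scaled to total UMIs. Their median was 0.06, with a mean of -0.54, a downward test and a median of -0.36 when scaled to total UMIs. Cxcl14 fell 23.8-fold, from 339.5 ± 124 to 14.2 ± 3.73 CPM. The growth factor gene Ereg was higher by a ratio of 79.8 (95% interval 21.7 to 665) on 2 basal-like counts. That call ended when the list genes took part in the clustering (adjusted p = 0.529) or the named genes did not (adjusted p = 0.0562, range 1.29e-33 to 0.529 over all alternatives).

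Of 10141 genes tested between spinous-like and basal-like cells by the edgeR quasi-likelihood test, 6581 passed an adjusted p of 0.05, 3363 higher and 3218 lower. Of these, 3562 differed at least 2-fold. Adjusted over the list alone, the counts of the lists above were unchanged except for cell cycle (1 rose, 52 fell), ribosomal proteins (46 rose) and transcription factors (27 rose, 13 fell). The median tested gene lay at -0.00 log2, and scaling to total UMIs moved it to -0.41 and the split to 2140 higher and 4989 lower. Among the 32 named genes, 6 had also helped to define the clusters: F3, Slurp2, Mboat2, Pbk, Igfbp7 and Serpinh1. Of the 32, 29 passed in every setting that tested them.

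**Figure D3:**
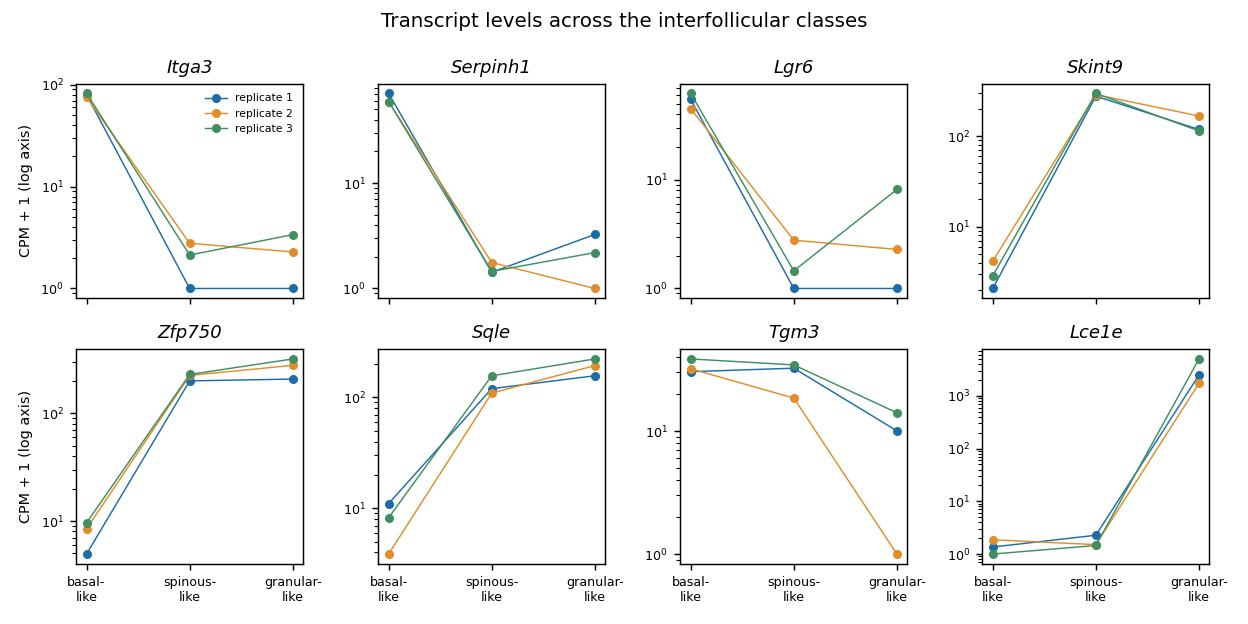
Points give the CPM + 1 with TMM scaling (vertical log axis) of 8 genes, 1 point per replicate and class. Basal-like, spinous-like and granular-like cells follow along the horizontal axis, and lines join the points of a replicate. Itga3 goes from 78.2 ± 3.50 CPM in basal-like to 0.97 ± 0.901 in spinous-like cells, and Lce1e from 0.745 ± 0.459 in spinous-like to 3083 ± 1729 in granular-like cells.

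Granular-like cells were compared with spinous-like cells to follow the last living step before cornification. Late cornified envelope genes were among the largest rises. Lce1e went from 0.745 ± 0.459 to 3083 ± 1729 CPM (SD, n = 3), 4189.6-fold (log2 12.03 ± 0.30 SE, adjusted p = 1.42e-69). Its neighbours Lce1a2, Lce1g, Lce1i and Lce1h rose between 2736-fold and 3056-fold. These genes are near-identical paralogs, so counts of single members are uncertain. Their paralogs Lce1a1, Lce1b, Lce1c and Lce1m were naming markers of granular-like cells, so these rises were favoured in advance. Lce1 genes filled the 10 leading genes of the smaller granular-like cluster (126 cells) and were absent from those of the larger (305 cells). Aif1l, an actin-binding protein gene, stood at 1060.2 ± 156 CPM and was higher by a ratio of 3898 (95% interval 1332 to 18914) on 3 spinous-like counts. Gja1, the gap junction protein connexin 43, led the fall, from 72.3 ± 29.6 to 2.05 ± 1.84 CPM (29.5-fold, log2 -4.88 ± 0.37, adjusted p = 2.93e-24). The focal adhesion gene Tns4 fell 12.1-fold and the transcription factor gene Mycl 12.5-fold. Also lower were Mettl7a1 13.7-fold, Clca3a2 16.1-fold and Ell3, which overlaps Serinc4, 15.9-fold.

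Genes of the cornified envelope, the protein shell of the dead cell, rose in 25 of 30 cases and fell in 4. Their median was 7.18 log2, or 6.59 with 2 zero-count genes at their bound (list test adjusted p = 6.49e-11, adjusted p = 0.0882 with an estimated correlation). Granular-like cells were named by other envelope genes, such as Lor, Flg and Ivl, so a rise of this list was favoured in advance. The transglutaminase gene Tgm3 ran against the list, 3.70-fold lower. Desquamation proteases and inhibitors rose in 26 and fell in 7 of 35 cases (list test adjusted p = 1.33e-06, adjusted p = 0.0882 with an estimated correlation). At the extremes, Stfa2, a stefin with near-identical paralogs, was higher by a ratio of 166 (95% interval 44.2 to 1401) but in 2 of 3 libraries. The protease gene Ctsc was lower by a ratio of 23.2 (95% interval 6.36 to 193) on 2 granular-like counts. Ceramide and barrier lipid genes rose in 25 and fell in 5 of 36 cases (list test adjusted p = 1.26e-06, adjusted p = 0.0882 with an estimated correlation). The lipase gene Lipn was higher by a ratio of 942 (95% interval 320.5 to 4579.7), and the lipoxygenase gene Alox12e 6.83-fold lower. With DESeq2 neither Lipn (adjusted p = 0.065), Stfa2 (0.266) nor Alox12e (0.0925) passed. Over all alternatives their adjusted p ran from 1.41e-244 to 0.065, 1.17e-20 to 0.266 and 1.09e-78 to 0.0925.

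Alarmin and antimicrobial genes rose in 11 and fell in 2 of 14 cases (list test adjusted p = 7.46e-05, adjusted p = 0.0882 with an estimated correlation). The cytokine gene Il18 went from 1.26 ± 0.732 to 1244 ± 105 CPM, 856-fold (log2 9.74 ± 0.23, adjusted p = 3.73e-73). Rnase4, which overlaps Ang, fell 5.75-fold. Cell death and nuclease genes rose in 11, fell in 2 and did not pass in 10 cases (list test adjusted p = 0.0162, adjusted p = 0.0931 with an estimated correlation), although scaling to total UMIs gave 9 rising and 7 falling. Dnase1l2, a nuclease that removes DNA during cornification, rose from 28.4 ± 6.50 to 854 ± 59.4 CPM (log2 4.88 ± 0.14), and Ripk1 fell 3.95-fold. Tight junction genes rose in 10 and fell in 3 of 18 cases (list test adjusted p = 0.0387, adjusted p = 0.0882 with an estimated correlation), or 8 and 7 with a median of -0.00 when scaled to total UMIs. Cingulin (Cgn) reached 651 ± 22.7 CPM from 67.9 ± 7.62, and tricellulin (Marveld2) fell 7.13-fold. Desmosome genes rose in 1 and fell in 4 of 11 cases (adjusted p = 0.263), or 1 and 8 scaled to total UMIs. Dsc1 was 2.38-fold higher and Dsc3 stood at 115 ± 50.5 against 1098 ± 20.1 CPM.

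Ribosomal protein genes fell in 45 and rose in 2 of 81 cases (list test adjusted p = 2.11e-06, adjusted p = 0.529 with an estimated correlation). Scaled to total UMIs 79 of them fell. Rps13 was 2.01-fold lower. Rpl36al, which overlaps another annotated gene, was 1.69-fold higher, a call lost when scaled to total UMIs (log2 0.06, adjusted p = 0.67, range 3.3e-14 to 0.67 over all alternatives). Nuclear oxidative phosphorylation genes fell in 29 and rose in 12 of 73 cases (list test adjusted p = 0.0496, adjusted p = 0.682 with an estimated correlation). Without replicate 1 the list did not pass (adjusted p = 0.0675, range 4.35e-06 to 0.0675 over all alternatives), and scaled to total UMIs 2 rose and 65 fell. Ndufa4 stood at 7691 ± 893 against 961 ± 23.4 CPM and Sdhd was 6.24-fold lower. Lysosome and proton pump genes rose in 18 and fell in 8 of 39 cases (list test adjusted p = 0.0496, adjusted p = 0.392 with an estimated correlation). Psap was 7.94-fold lower. The lysosome list's call ended in most alternatives, such as without replicate 1 (adjusted p = 0.0661) and without replicate 2 (adjusted p = 0.101, range 0.0287 to 0.27 over all alternatives). It also ended when scaled to total UMIs, where 10 rose, 16 fell and the median turned to -0.42.

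Transcription factor genes split into 21 rising and 18 falling (adjusted p = 0.406), a balance that scaling to total UMIs turned to 16 and 21. Prdm1, which encodes Blimp1, rose from 4.40 ± 2.46 to 553 ± 81.2 CPM (log2 6.86 ± 0.17), and Foxn1 fell 11.2-fold. Cholesterol synthesis genes rose in 13 and fell in 4 of 24 cases (adjusted p = 0.0861, 0.00767 with the second seed, range 0.00767 to 0.476 over all alternatives), but scaled to total UMIs 7 rose and 11 fell. The cholesterol carrier gene Stard4 was 4.12-fold higher and mevalonate kinase (Mvk) 1.74-fold lower with TMM. Calcium handling genes rose in 11 and fell in 12 of 31 cases (adjusted p = 0.938). Their median was 0.16, with a mean of -0.04, a downward test and a median of -0.53 when scaled to total UMIs. S100a3, which overlaps S100a2, was 39.0-fold higher, and S100a11 8.60-fold lower.

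In all, 5733 of 10141 genes passed between granular-like and spinous-like cells, 2831 higher and 2902 lower, and 3883 of these differed at least 2-fold. The counts adjusted over the list alone were the same apart from lysosome genes (19 rose). The median tested gene lay at -0.15 log2 with TMM, -0.85 with total UMIs and -0.03 with DESeq2. The split became 1675 higher and 5491 lower with total UMIs, which called 88 genes in the opposite direction in granular-like against spinous-like cells. With DESeq2 it was 2740 higher and 2250 lower. Of the 37 named genes, 5 had also helped to define the clusters and 33 passed in every setting that tested them.

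Follicle-like and basal-like cells were compared to describe how follicle keratinocytes differ from basal ones. A difference found here need not be particular to the follicle-like class. Ctgf, a connective tissue growth factor, stood at 344 ± 129 CPM (SD, n = 3) and was higher by a ratio of 1198 (95% interval 399 to 5902) on 3 basal-like counts (adjusted p = 4.96e-41). The Wnt inhibitor gene Wif1 was higher by a ratio of 1165 (95% interval 196 to 47319) and the parathyroid hormone-related gene Pthlh by 899 (95% interval 237 to 7611). The protease inhibitor genes Wfdc3 and Serpinb11 were higher by 1132 (95% interval 302 to 9535) and 1198 (95% interval 202 to 48634), and the matrix gene Aspn at least 233-fold. Among the largest falls, the cell cycle genes Ube2c and Top2a had no counts in follicle-like cells, at least 26.2-fold and 25.8-fold lower. The same held for Cenpf (at least 17.0-fold), Nusap1 (15.2-fold), Pclaf (13.2-fold) and the peptide hormone gene Pyy (17.2-fold). Il33, an alarmin cytokine gene of 109.6 ± 15.6 CPM in basal-like cells, was at least 11.4-fold lower. TMM factors were 1.42, 1.44 and 1.19 in follicle-like and 1.05, 1.01 and 1.06 in basal-like profiles. On total UMIs the bounds of these falls would be smaller.

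Hedgehog pathway genes rose in 5 of 8 cases and none fell (list test adjusted p = 1.52e-05, adjusted p = 0.00399 with an estimated correlation). The call ended without replicate 2 (adjusted p = 0.0562) and in cells of 1500 or more genes (adjusted p = 0.166), in a range of 3.45e-07 to 0.166 over all alternatives. The latter setting also changed the follicle-like class, from 108 to 154 cells, with 0 cells named sebocyte-like. The pathway's transcription factor gene Gli1 stood at 41.5 ± 5.79 CPM and was higher by a ratio of 216 (95% interval 49.0 to 1975) on 2 basal-like counts. Cell cycle genes fell in 36 of 53 cases, or 45 adjusted over the list alone, 28 scaled to total UMIs and 19 with DESeq2 (list test adjusted p = 1.08e-19, adjusted p = 0.00399 with an estimated correlation). Their median was -3.38 log2, or -2.23 with 21 zero-count genes at their bound. Leaving out the basal-like clusters led by cell cycle genes ended that call (median -1.25, adjusted p = 0.253, range 1.98e-26 to 0.253 over all alternatives) and those of Ube2c, Top2a, Cenpf and Nusap1 (adjusted p between 0.0714 and 0.677).

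Wnt pathway genes rose in 6 and fell in 4 of 23 cases (adjusted p = 0.081, 0.0305 without replicate 1, range 0.0272 to 0.60 over all alternatives). Their median was 0.09, with a mean of -0.08 and an upward test, and the receptor gene Fzd10 was at least 4.26-fold lower. Cytokine and chemokine genes rose in 6 and fell in 5 of 22 cases (adjusted p = 0.081, 0.0251 without replicate 1, range 0.0251 to 0.384). Here the median was 0.32, with a mean of -0.14 and an upward test. Cd200, an immune-inhibitory surface protein of the follicle bulge, rose from 1.32 ± 0.352 to 120.4 ± 59.2 CPM (log2 6.42 ± 0.54, adjusted p = 4.81e-20). Bmp4 was at least 2.99-fold lower (adjusted p = 0.0689 without replicate 3, range 7.07e-05 to 0.0689). Basement membrane adhesion genes rose in 4 and fell in 1 of 24 cases (adjusted p = 0.345, 0.0309 with the second seed, range 0.0309 to 0.978). This list had a median of -0.17, a mean of 0.23, an upward test and medians of 0.20 scaled to total UMIs and 0.18 with DESeq2. The collagen IV gene Col4a2 was 19.3-fold higher (adjusted p = 0.00218) and Itga3 2.75-fold lower (adjusted p = 0.016). Itga3 did not pass without replicate 2 (adjusted p = 0.147) or replicate 3 (adjusted p = 0.253), in a range of 3.73e-06 to 0.254 over all alternatives.

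Immediate early and heat shock genes rose in 3 and fell in 7 of 34 cases, or 6 and 9 adjusted over the list alone, but scaling to total UMIs reversed the balance to 6 rising and 3 falling and DESeq2 to 6 and 2. As a list they did not pass (adjusted p = 0.14, 0.032 without replicate 3, range 0.00328 to 0.603). Egr2 was 16.9-fold higher (adjusted p = 0.194 without replicate 2, range 4.64e-13 to 0.924) and Atf3 2.93-fold lower (adjusted p = 0.203 without replicate 3, range 7.51e-05 to 0.203). In the cholesterol synthesis list 1 of 24 genes fell (adjusted p = 0.711). It was the synthase gene Hmgcs1, 6.56-fold lower (adjusted p = 1.76e-07), and both turned upward in cells of 1500 or more genes (Hmgcs1 log2 0.58, list median 1.92, list adjusted p = 1.17e-10, range 1.17e-10 to 0.978). In that setting 154 cells were follicle-like, against 108, and 0 were sebocyte-like, against 102. The follicle-like class was thus not the same set of cells. In the antimicrobial and alarmin list 2 of 14 genes fell (adjusted p = 0.228). The median was -1.32, or -0.56 with 5 zero-count genes at their bound and 0.27 with DESeq2.

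Of 10141 genes, 1226 passed between follicle-like and basal-like cells, 458 higher and 768 lower. Leaving out any replicate lowered the count to between 728 and 773. The split also turned with scaling, to 631 higher and 324 lower with total UMIs (median gene 0.09 log2, against -0.25 with TMM). With DESeq2 it was 774 higher and 269 lower (0.14). DESeq2 did not call Aspn, Wif1, Gli1, Col4a2, Itga3 or Atf3, with adjusted p between 0.0628 and 0.452. The other lists' counts adjusted over the list alone were the same, and 6 of the 22 named genes had helped to define the clusters. In every setting that tested them, 9 of the 22 passed, and Gli1 was tested in only 11 of 21 alternatives.

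**Figure D4:**
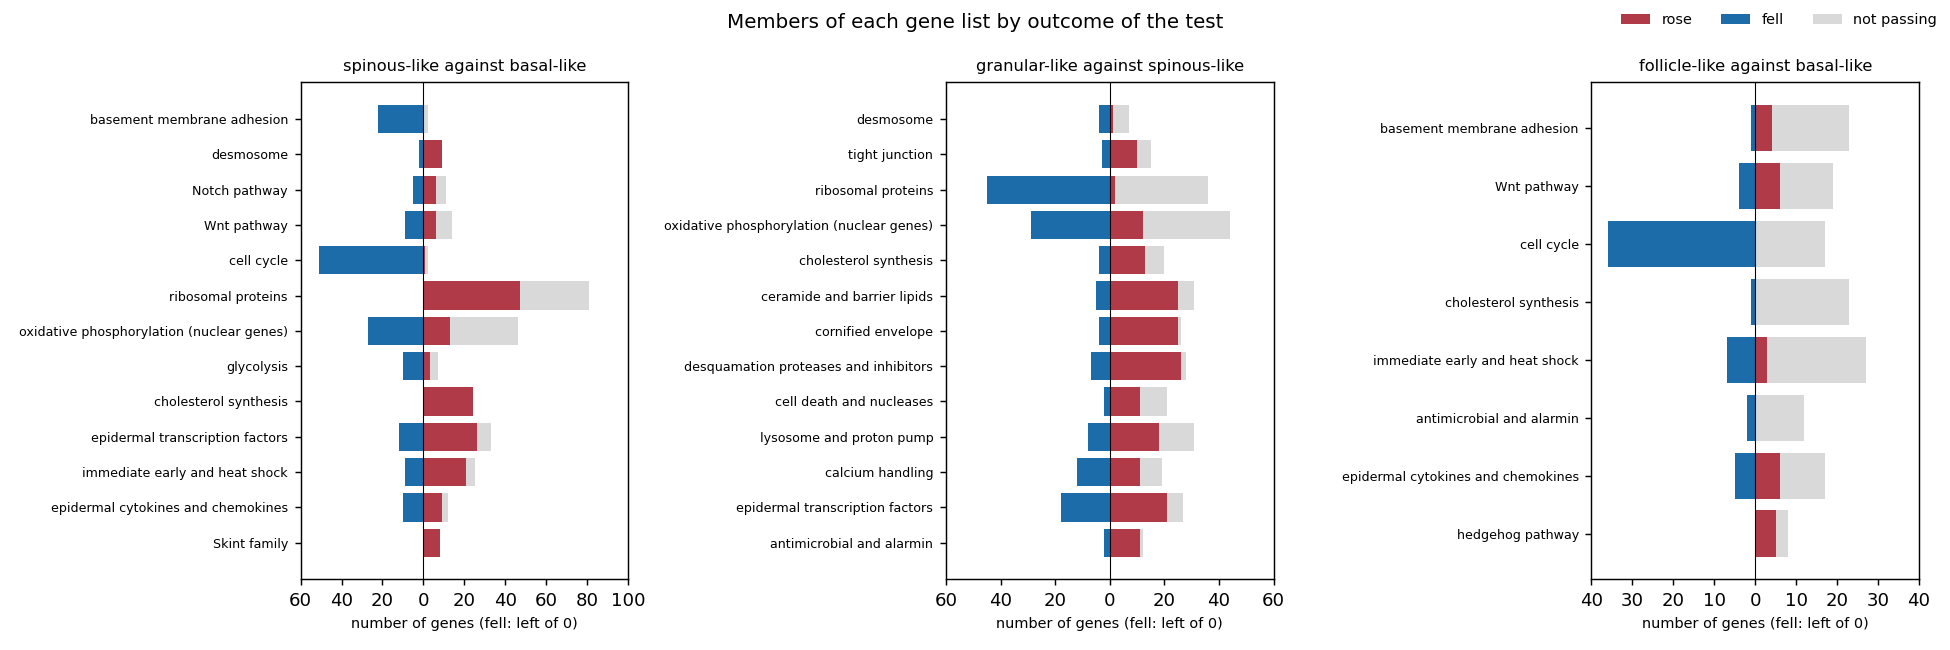
Bars give, for each gene list (vertical axis), the number of tested genes (horizontal axis) that rose (right of 0), fell (left of 0) or did not pass (grey) in the 3 planned comparisons, with TMM scaling. Cholesterol synthesis genes (24 of 24 rose) and cell cycle genes (51 of 53 fell) moved together in spinous-like cells, while the balance turned when scaled to total UMIs for granular-like cholesterol, lysosome and transcription factor genes, spinous-like Notch genes and follicle-like immediate early genes, and with DESeq2 for granular-like calcium and follicle-like immediate early genes.

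The immune classes were compared to show what separates the antigen-presenting cells of the epidermis from its resident T cells. The 6 named genes with the largest rises in Langerhans-like cells (n = 2 libraries) had no counts in T-like cells (n = 3). H2-DMa, which loads peptides onto class II molecules, stood at 2441 ± 100.1 CPM (SD) and was at least 52.5-fold higher (adjusted p = 4.31e-14). Its partner H2-DMb1 was at least 38.9-fold higher. The adhesion gene Epcam, the signalling adaptor gene Tyrobp and the histocompatibility genes H2-M2 and H2-M5 were at least 42.1-fold, 43.2-fold, 33.7-fold and 35.9-fold higher. In the other direction Thy1, a surface antigen of T cells, stood at 1488 ± 415 CPM in T-like cells and had no counts in Langerhans-like cells. It was at least 60.3-fold lower in the latter (adjusted p = 8.41e-12). The cathepsin gene Ctsw (at least 47.7-fold), the receptor signalling adaptor gene Lat (35.8-fold), the granule proteoglycan gene Srgn (27.2-fold), Ptprcap (31.2-fold) and Sytl3 (17.9-fold) were lower in the same way. These bounds rest on TMM factors of 3.48, 1.63 and 2.22 in T-like and 1.10 and 1.09 in Langerhans-like profiles. On total UMIs the bounds of the rises would be smaller and those of the falls larger.

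Antigen presentation genes rose in 12 of 19 cases and none fell, or 13 adjusted over the list alone, 4 when scaled to total UMIs and 7 with DESeq2. Their median was 2.78 log2, or 2.28 with 7 zero-count genes at their bound (list test adjusted p = 1.11e-10, adjusted p = 0.00133 with an estimated correlation). Cytotoxic and T cell receptor signalling genes fell in 7 of 17 cases, or 8 falling and 3 rising adjusted over the list alone, and 2 falling with DESeq2. The median of this list was -3.82, or -1.99 with 8 genes at their bound (list test adjusted p = 1.56e-07, adjusted p = 0.000809 with an estimated correlation). Langerhans-like cells were named by class II genes such as Cd74 and H2-Aa, and T-like cells by receptor genes such as Cd3e. The directions of the antigen presentation and T cell lists were thus favoured in advance by the naming. Chemokine and cytokine receptor genes rose in 1 and fell in 3 of 15 cases, or 2 and 5 adjusted over the list alone, 0 and 4 scaled to total UMIs and 0 and 0 with DESeq2 (list test adjusted p = 0.00674, adjusted p = 0.0242 with an estimated correlation). Without replicate 2 the median was 3.63 (adjusted p = 0.52, or 0.112 with thinned profiles, range 0.000502 to 0.52 over all alternatives). The interleukin 6 receptor gene Il6ra was higher by a ratio of 16.1 (95% interval 2.69 to 655), with adjusted p = 0.0596 and 0.0548 without replicates 2 and 3 (range 0.000116 to 0.28). Il2rg, the shared interleukin receptor chain, was at least 16.6-fold lower, with adjusted p = 0.0665 without replicate 2 (range 7.38e-07 to 0.78).

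Ribosomal protein genes rose in 37 of 81 cases, or 58 adjusted over the list alone (list test adjusted p = 2.56e-36, adjusted p = 0.0644 with an estimated correlation), but scaled to total UMIs 3 rose and 1 fell, and with DESeq2 23 rose. With only the 2 classes in the fit the list did not pass (adjusted p = 0.599, range 1.66e-79 to 0.599). Rps25 was 4.35-fold higher (adjusted p = 0.0805 without replicate 3, range 5.15e-05 to 0.345). Lysosome genes rose in 3 and fell in 1 of 33 cases, or 1 and 1 scaled to total UMIs and 1 and 0 with DESeq2 (list test adjusted p = 0.0139, adjusted p = 0.0644 with an estimated correlation), and the list did not pass when scaled to total UMIs (adjusted p = 0.115, range 8.17e-06 to 0.388). Cd63 was higher by a ratio of 24.1 (95% interval 4.13 to 973), but not with profiles thinned to the same total (adjusted p = 1, range 1.33e-07 to 1). Ctsd was lower by 15.9 (95% interval 2.13 to 706) (adjusted p = 0.636 without replicate 3, range 0.000261 to 0.78). Glycolysis genes rose in 3 of 13 cases, or 4 adjusted over the list alone, but 1 with DESeq2 and 1 scaled to total UMIs, where the median of 0.75 turned to -0.07. As a list they did not pass (adjusted p = 0.0554, 0.0263 without replicate 2, range 0.00372 to 0.526), and Gpi1 was higher by a ratio of 9.05 (95% interval 2.94 to 45.3). The call of Gpi1 ended with profiles thinned to the same total (adjusted p = 0.78, range 0.000224 to 0.78). Immediate early and heat shock genes rose in 6 and fell in 1 of 32 cases, or 9 and 1 adjusted over the list alone, but 1 and 1 with DESeq2 or scaled to total UMIs, where the median of 0.89 became -0.00. That list's adjusted p was 0.0593, against 0.0437 and 0.026 without replicates 2 and 3 (range 0.000416 to 0.771). Ier3 was higher by a ratio of 39.0 (95% interval 10.6 to 325) (adjusted p = 0.0517 with profiles thinned to the same total, range 8.29e-14 to 0.0517). Btg1 was 3.34-fold lower (adjusted p = 0.116 without replicate 3, range 1.51e-08 to 0.444).

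Among 5482 genes tested between the immune classes, 382 passed, 300 higher and 82 lower in Langerhans-like cells. This comparison did not meet the planned minimum of 10 cells per profile, since T-like cells reached it in 1 library, and it was run at 3 cells, a choice made after the data had been seen. Scaled to total UMIs, 76 genes were higher and 146 lower (median gene -0.08 log2, against 0.58 with TMM), and with DESeq2 119 and 54 (0.02). Leaving out replicate 1, 2 or 3 gave 268, 245 and 132 genes, the last 2 counts with a single Langerhans-like profile. DESeq2 did not call H2-M2, H2-M5, Ctsw, Lat, Srgn, Ptprcap, Sytl3, Il6ra, Il2rg or Ctsd, with adjusted p between 0.0774 and 0.705, and 6 of the 20 named genes had helped to define the clusters. With profiles thinned to the same total H2-M2, H2-M5, Ctsw, Lat, Srgn and Ptprcap were not called either (adjusted p between 0.0531 and 0.292). Ptprcap, Il2rg and Ctsd overlap other annotated genes on the same strand, so their counts are less certain. In every setting that tested them, 5 of the 20 passed.

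The genes named most often lie at these places of the mm10 assembly (GRCm38, GENCODE M21), all as protein-coding genes, with the measured UMIs counted over the whole gene. In the spinous-like comparison these are Dkkl1 (chromosome 7, 45207519 to 45212147), Itga3 (chromosome 11, 95044474 to 95076801), Sqle (chromosome 15, 59315077 to 59331192), Zfp750 (chromosome 11, 121510978 to 121519333) and Skint9 (chromosome 4, 112385969 to 112433985). For granular-like cells they are Lce1e (chromosome 3, 92707401 to 92709074), Il18 (chromosome 9, 50554827 to 50581840), Prdm1 (chromosome 10, 44437177 to 44528501), Dnase1l2 (chromosome 17, 24440081 to 24443105) and Gja1 (chromosome 10, 56377330 to 56402513). For follicle-like cells they are Ctgf (chromosome 10, 24595442 to 24598683), Wif1 (chromosome 10, 121033960 to 121100650), Gli1 (chromosome 10, 127329882 to 127341974) and Il33 (chromosome 19, 29925114 to 29960718), and for the immune classes H2-DMa (chromosome 17, 34119541 to 34139101, overlapping an annotated transcript on the same strand) and Thy1 (chromosome 9, 44043384 to 44048579). The identifiers in the deposited gene table are ENSMUSG00000030792 for Dkkl1, ENSMUSG00000001507 for Itga3, ENSMUSG00000068889 for Lce1e, ENSMUSG00000039217 for Il18, ENSMUSG00000020218 for Wif1 and ENSMUSG00000037649 for H2-DMa.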

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

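Of the alternatives below, cells of 1500 or more genes, named genes left out of the clustering, cell cycle clusters left out, the 3-cell minimum, the immune fit with T-like cells of 1 library at the planned 10-cell minimum and the whole sebocyte-like comparison were chosen after seeing the data, and the others were planned. Over all alternatives, 3077 values of named genes kept their direction and their side of the threshold, 179 lost the call in the same direction and 3 reversed, while list tests stayed on their side of the threshold in 1202 cases, passed or not, and 51 calls were gained, 35 lost and 1 reversed. Some named genes were filtered out or had no adjusted p in some alternatives, and those settings do not count here. Named genes that passed in every setting that tested them were 29 of 32 in spinous-like against basal-like cells, 33 of 37 in granular-like against spinous-like cells, 9 of 22 in follicle-like against basal-like cells, 5 of 20 in Langerhans-like against T-like cells and 25 of 51 in sebocyte-like against basal-like cells. Thinning every profile to the total of the smallest (60297 UMIs for follicle-like, 5273 for T-like and 75677 for sebocyte-like) left 299, 22 and 307 called genes.

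With profiles of 3 or more cells in the fit, which adds T-like profiles of replicates 1 and 3 and has 5482 genes tested, the counts fell to 3834 genes in spinous-like against basal-like cells, 3655 in granular-like against spinous-like cells and 731 in follicle-like against basal-like cells. The immune comparison gave 128 genes with T-like cells of 1 library at 10 or more cells, 173 with DESeq2, 708 with all UMI counts, 98 with only the 2 classes and 222 when scaled to total UMIs. Leaving out a replicate gave 4762 to 6052 genes for spinous-like, 4278 to 5234 for granular-like, 728 to 773 for follicle-like, 132 to 268 for Langerhans-like and 699 (without replicate 3) to 1167 for sebocyte-like cells. At 10 cells a single T-like profile, and without replicate 2 or 3 a single Langerhans-like profile, remained and was assumed to vary like the other classes. Without the replicate block the counts were 6039, 5477, 1061, 386 and 1260.

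Shares moved by more than 1 SD with the filters and the clustering. Cells of 1500 or more genes gave basal-like 43.4%, spinous-like 32.1%, follicle-like 3.46%, sebocyte-like 0%, T-like 0.240% and unnamed 12.7%, and hence no sebocyte-like comparison. Keeping doublets gave basal-like 45.5% and unnamed 12.7%, and keeping list genes in the clustering basal-like 46.2% and spinous-like 24.4%. The second seed gave basal-like 47.0%, spinous-like 31.9%, granular-like 10.1%, follicle-like 1.69%, sebocyte-like 2.38% and unnamed 6.01%. Centred genes gave spinous-like 23.02% and unnamed 24.6%, and a mitochondrial limit of 20% spinous-like 26.9%, granular-like 4.64%, sebocyte-like 2.69% and unnamed 21.9%. Leaving named genes out of the clustering gave spinous-like 23.3% and unnamed 21.4%. Resolution 0.6 gave spinous-like 24.8%, granular-like 4.84% and unnamed 24.9%, and resolution 1.5 granular-like 4.83% and unnamed 21.2%. All UMI counts gave granular-like 10.1%, follicle-like 1.81% and sebocyte-like 2.51%.

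Reversed, for named genes in their sign and for lists in a passing test's direction, were Hmgcs1 in follicle-like against basal-like cells (0.58 log2 in cells of 1500 or more genes), the cholesterol synthesis list there (median 1.92) and Gas1 in sebocyte-like against basal-like cells (0.0190 with all UMI counts, 0.32 with the second seed). In cells of 1500 or more genes the follicle-like class held 154 cells, against 108, and 0 cells were sebocyte-like. The follicle-like reversals there thus compare another set of cells. For all these reversals and for the moved counts and shares whose reason is not stated, the cause was not tested.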

Other observations

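The sebocyte-like comparison, the splits of profiles and the tests of the 3 patterns below were chosen after their results had been seen, apart from the keratin test of free RNA, which was written before. Sebocyte-like cells (102 cells) were compared with basal-like cells, with CPM scaled by TMM. The aldo-keto reductase gene Akr1c18 stood at 513 ± 111 CPM (SD, n = 3) against 3.80 ± 6.33, 166-fold higher (log2 7.38 ± 0.28 SE, adjusted p = 9.72e-49). Further rises were Dpysl3 152-fold and Cd200 143-fold. The cytochrome P450 gene Cyp2f2 was at least 286-fold higher (adjusted p = 0.20 with DESeq2, range 4.72e-37 to 0.20), and Gata6, a transcription factor of the sebaceous duct and upper follicle, was higher by a ratio of 494 (95% interval 80.1 to 20329.7). Ube2c (at least 40.6-fold lower) and the histone gene Hist1h1b (24.8-fold) led the falls, and both lost their call without the basal-like clusters led by cell cycle genes (adjusted p = 0.546 and 0.0748). The protease genes and inhibitors Serpinb7 and Mmp3 were at least 15.1-fold and 14.7-fold lower, Antxr1 and Crispld2, which overlaps another gene, at least 14.2-fold, and Thy1 lower by a ratio of 71.6 (95% interval 19.8 to 592).

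Cholesterol synthesis genes rose in 18 and fell in 1 of 24 cases, or 20 and 1 adjusted over the list alone (list test adjusted p = 1.38e-13, adjusted p = 0.272 with an estimated correlation). Ceramide and barrier lipid genes rose in 13 of 36 cases, or 14 with 1 falling adjusted over the list alone (list test adjusted p = 2.16e-06, adjusted p = 0.243 with an estimated correlation), but not with thinned profiles (adjusted p = 0.0579, range 2.76e-07 to 0.0579). They were led by the hydroxylase gene Fa2h, at least 2482-fold higher in 2 of 3 libraries (adjusted p = 0.0736 with DESeq2, range 1.76e-280 to 0.0736). Sebocyte-like cells were named by other lipid genes, such as Scd1 and Fasn, so rises of lipid genes were favoured in advance. Cell cycle genes fell in 41 of 53 cases, or 47 over the list alone (median -3.09, or -2.37 with 12 zero-count genes at their bound, list test adjusted p = 4.77e-23, adjusted p = 0.147 with an estimated correlation), a call that ended without the cell cycle clusters (adjusted p = 0.385, range 2.73e-28 to 0.385). Basement membrane adhesion genes fell in 8 of 24 cases, or 10 over the list alone (median -0.83, or -0.71 with zero counts at their bound, adjusted p = 0.00177, 0.422 with an estimated correlation). The naming of basal-like cells by other adhesion genes favoured a fall of this list in advance. The call of that list ended with thinned profiles (adjusted p = 0.162), a mitochondrial limit of 20% (adjusted p = 0.15) and the second seed (adjusted p = 0.0787, range 0.000184 to 0.162). Itga3 was 7.70-fold lower (adjusted p = 0.0658 with profiles thinned to the same total, range 3.25e-08 to 0.0658). Ribosomal protein genes fell in 12 of 81 cases, or 4 scaled to total UMIs and 1 with profiles of 3 or more cells (adjusted p = 2.48e-13, 0.603 with an estimated correlation). Oxidative phosphorylation genes rose in 7 and fell in 2 of 73 cases, or 13 and 1 scaled to total UMIs and 20 and 1 with DESeq2 (adjusted p = 0.0267, 0.715 with an estimated correlation). Without replicates 2 and 3 that list had adjusted p = 0.412 and 0.407 (range 2.99e-10 to 0.412). Of 10141 genes 1473 passed, 681 higher and 792 lower (median gene -0.19 log2), and the split became 794 and 518 with total UMIs (-0.02) and 820 and 332 with DESeq2 (0.04). Without replicate 3 the count was 699, and 25 of the 51 named genes passed in every setting that tested them.

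The other lists did not pass in sebocyte-like cells, with list adjusted p of 0.0594 for tight junction genes (4 rose, 1 fell) and 0.295 or more for the rest. Some passed in alternatives: tight junction (range 0.000189 to 0.272), desmosome (0.0135 to 0.816), cytokine (0.0246 to 0.988), lysosome (0.0451 to 0.446) and Skint genes (0.0451 to 0.981). Lysosome genes rose in 7 cases and none fell, led by the proton pump gene Atp6v1c2 (26.3-fold). Members rose and fell in Wnt (3 and 7, Fzd7 14.6-fold higher, but adjusted p = 0.0508 without replicate 3, range 2.17e-13 to 0.0829), Notch (1 and 2), glycolysis (3 and 3, Ldhb 8.72-fold higher), cornified envelope (4 and 2), desquamation (6 and 5, Klk7 24.6-fold higher), cell death (1 and 1), calcium (2 and 6) and transcription factor (10 and 12) genes. They did so too in immediate early (6 and 9, Egr2 25.3-fold higher), antimicrobial (3 and 3, Il33 5.77-fold lower, but adjusted p = 0.0593 with thinned profiles, range 4.33e-09 to 0.0593), cytokine (4 and 5), Skint (3 and 2), antigen presentation (4 and 1) and T cell (1 and 3) genes, while desmosome genes showed 1 rise, hedgehog genes 1 fall and receptor genes 4 falls. With DESeq2, which differs in scaling and test, more members rose than fell among Notch, calcium, transcription factor, immediate early and cytokine genes. Scaled to total UMIs, this also held for Notch (1 and 0), calcium (5 and 4), transcription factor (12 and 10) and immediate early (7 and 4) genes, while cytokine genes showed 4 and 4. Adjusted over the list alone the counts became 3 and 8 for Wnt, 3 and 7 for glycolysis, 7 and 1 for lysosome, 12 and 13 for transcription factor, 6 and 12 for immediate early, 4 and 4 for antimicrobial and 4 and 6 for cytokine genes. Median, mean and test differed in sign for Notch, glycolysis, cornified envelope, desquamation, cell death, lysosome, transcription factor, antimicrobial, cytokine, Skint and antigen presentation genes.

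No cell of replicate 1 was named Langerhans-like, where 9.14 were expected from the other replicates. Counting error from too few sampled cells does not account for it alone (Fisher's exact test, 2-sided, p = 0.000396). That test takes cells as independent draws, so it does not cover variation of shares between libraries. Nor does removal by the filters account for it, though barcodes dropped before deposition, when cells were called, could not be examined. Of replicate 1's barcodes left out of the analysis, 0 held 10 or more Langerhans marker UMIs (lower Poisson limit 5 around 11.4 expected). Among all its barcodes 2 reached that level, with 13 UMIs each (1 basal-like and 1 spinous-like cell), against 28 and 23 in the others (Fisher's exact test, 2-sided, p = 0.00355), and Cd207 had 4 UMIs against 228 and 266. A loss of all immune cells in that preparation could explain the pattern, but T-like cells, at a ratio of 0.784 (95% interval 0.148 to 2.69) to the other replicates, are too few for it to be told apart from a loss of Langerhans-like cells alone. No biological explanation was tested, since the design has 1 group.

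An unnamed cluster held 127 barcodes with under 1% mitochondrial UMIs and a median of 1372 UMIs. Free RNA in all of these droplets would keep basal and spinous keratins at 1 ratio in every barcode of a library, but the ratio differed in each replicate (chi-square statistic over the barcodes against 10000 binomial simulations, p = 0.0001, the smallest they can give). The test cannot exclude free RNA in part of the barcodes. Only 1 of 30, 7 of 27 and 1 of 70 barcodes of replicates 1 to 3 held basal keratins alone, and 0, 1 and 3 spinous keratins alone. Spinous keratins took 0.532% ± 0.196 of UMIs, against 0.214% ± 0.0566 in basal-like cells. Isolated nuclei would be rich in nuclear-retained RNAs, but these reached at most 0.0584, and Malat1 at most 0.147, of their share in basal-like cells. The former value rests on 0, 1 and 3 UMIs of such RNAs in replicates 1 to 3. Ribosomal protein transcripts made up 26.7% ± 0.885 of UMIs against 29.7% ± 1.61 (SD over the replicates), and Gm42418, a sign of RNA quality, 8.64% ± 3.34 against 1.86% ± 0.205, while the cluster's other 112 barcodes had 20.1% ± 20.6 with Malat1 near the basal-like level (0.767% ± 0.248 against 0.785% ± 0.124). Pieces of cytoplasm without nucleus and mitochondria are thus a candidate explanation, as a hypothesis. Few mitochondrial UMIs were how these barcodes were picked, so they lend it no support. The whole cluster was also led by cell cycle genes such as Mki67 and Birc5, for which no reason was tested. Free RNA in part of the barcodes stays open, poor RNA quality was not tested and stays open, and no biological explanation was tested.

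When scaled to total UMIs, the median gene of granular-like cells fell relative to spinous-like cells, by -0.68 ± 0.0860 log2 (SD over 3 libraries, unfitted values with 1 CPM added, where the fitted value is -0.85). The 10 most abundant genes of granular-like cells, Lor first, took 20.1% ± 0.565 of UMIs there and 5.52% ± 0.0638 in spinous-like cells, and could lower all other genes on that scale. Without these genes the median was still -0.49 ± 0.0869, so they are not the whole cause. What accounts for the rest stays open, and no biological explanation was tested.

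Splitting the 6 profiles of each comparison in the 10 possible ways is too few for a share under 0.05. The real division gave 6581 genes for spinous-like, 5733 for granular-like, 1226 for follicle-like and 1473 for sebocyte-like cells, the most in each case (1 of 10 splits), and the highest of the others gave 0, 0, 1 and 75. The classes came from clustering the same cells, and every other split mixed the classes. The real division was thus favoured in advance, and no conclusion about chance is drawn.

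Markers of other cell types were scarce in the 6078 barcodes. UMIs of Schwann cell markers numbered 1658 (9 barcodes with 5 or more), melanocyte markers 632 (10 barcodes), neutrophil markers 410 (0), fibroblast markers 398 (7), red blood cell markers 261 (0), alpha-beta T cell markers 248 (0), endothelial markers 187 (6), macrophage markers 80 (2), Merkel cell markers 8 (0), chondrocyte markers 1 (0) and mast cell markers 0. Fibroblast marker UMIs were 249 in replicate 1 against 54 and 95. Xist had 2920, 4116 and 5186 UMIs in replicates 1 to 3, and 4 Y-linked genes had 1, 0 and 0.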
